A study of Pseudotsuga menziesii with 66 samples.

How the data were processed

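RNA from needles of 5 Douglas-fir trees collected on 16 dates was made into poly(A) libraries that keep the strand by marking the second strand with dUTP, and sequenced on a HiSeq 2000, per the labels' protocols. The submitters' processing notes name CASAVA 1.8, Bowtie2 2.2.3 and DESeq. The transcript reference that the reads were aligned to and the counting tool and its settings are not given in the sources used here, so how reads of near-identical transcripts or of overlapping transcripts on opposite strands were assigned is not known.

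A count table deposited by the authors holds whole-number counts of 199471 transcripts in 66 libraries, of which 28846 transcripts have no count in any library. Another table deposited by the authors holds normalized signal values of 36145 transcripts. When compared with the count table, each of its columns was the counts divided by 1 factor per library, with a largest relative deviation of 5.8e-15, and its transcripts held 97.6% to 99.4% of each library's counts. The last table deposited by the authors holds interpolated signal values for 2 series over 16 dates. On the first date its values equalled the mean of CCTO44 and CCTO90 in the first series and of CCTO43, CCTO46 and CCTO89 in the second, within a relative deviation of 5e-09, and on the last date the second series equalled CCTO43, within 4.8e-09. The interpolated values have no replicates and served only as an alternative for peak days. All main tests were run on the counts as deposited. Each column was matched to its library by the tree and date in its name, and no column was left without a library.

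Groups were the 16 collection dates and replicates were the trees. Because the same trees return on each date and are missing on different dates, the tree was a block in every model. This pairing was also checked in the values: after removing date means, 64 of 66 libraries correlated best with the other libraries of their own tree, with a median correlation of 0.51 within trees and -0.15 between trees. No 2 libraries agreed within sampling noise; the closest pair had a chi-square per degree of freedom of 9.19, and the median over 2145 pairs was 182. The labels name no sequencing batches beyond pools of 6 libraries, whose members they do not give.

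Tests used edgeR 4.0.16 with limma 3.58.1 in R 4.3.3. Transcripts were kept by filterByExpr with the date as group and a minimum count of 10, which left 60931. Normalization factors were TMM, and quasi-likelihood models were fitted with robust dispersion and tested with F tests, followed by Benjamini-Hochberg adjustment within each test. Log2 values for descriptions used a prior count of 2. All 66 libraries entered each model except that of the tree by season terms, which used the 4 trees with 13 or more dates. Tested were all dates together, a cosine and sine with a period of 1 year, the contrasts 6 Jan against 17 Jun 2011, 10 Mar against 7 Oct 2011 and 26 Oct 2011 against 27 Oct 2010, the 15 pairs of successive dates, the trees, and the tree by season terms. The ratio of peak to trough comes from the amplitude of the fitted curve, and peak days were set against windows of 30 days on each side of the solstices and equinoxes. Detected transcripts were compared after drawing 9924771 counts from each library without replacement.

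Transcripts named in the text were chosen by a rule: a mean of at least 10 CPM over all libraries, an adjusted p under 0.05, the same direction in every tree with both dates (for annual curves, the curve of each of 4 trees peaking within 45 days of the joint one), and then the 2 largest in each direction per comparison. Gene lists prepared for the tissue were not used, because the files do not pair identifiers with names. Samples, tests, the rule for names and most alternatives were fixed before the data were examined; alternatives added later are named as such where their values are given.

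The tests were run on simulated counts with known changes among 60931 transcripts. For winter against summer, edgeR recovered 7% of 100 transcripts changed 2-fold and 64% of those changed 4-fold, with 4 false calls. For March against October the shares were 7% and 53%, and for October 2011 against October 2010 4% and 44%. For annual curves with a peak-to-trough ratio of 2-fold and 4-fold they were 67% and 97%, with a median error of the peak day of 8.6 and 3.9 days. For the tree by season terms, with such curves turned upside down in CCTO90, they were 25% and 86%. For differences between trees they were 65% and 94%. For all dates together, with a single date changed, they were 10.3% and 60.3%. Small changes between pairs of dates were thus mostly missed in the simulation. It changed few transcripts and used 1 dispersion, 0.0976, for all of them. In the data 59.9%, 34.3% and 30.1% of transcripts were called in the 3 contrasts, so the adjusted p there allows larger unadjusted p. The simulated shares are therefore not those of the data.

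Alternatives were size factors by RLE and by the upper quartile, no filter on low counts, a mean of at least 5 CPM, an adjusted p under 0.01, models without each tree, without the block and without the library under 50% of the median depth, DESeq2 1.42.0, limma-voom, a fit to date means, the date as a correlated block, 2 cycles per year, and other choices of dates. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.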

Results

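Needles of 5 young Douglas-fir trees (Pseudotsuga menziesii) were sampled for RNA on 16 dates between 27 Oct 2010 and 26 Oct 2011. The trees, named CCTO43, CCTO44, CCTO46, CCTO89 and CCTO90, stood in a common garden in Oregon and came from low-elevation Siskiyou seed of 2 localities, CCTO44 and CCTO90 from the higher and the others from the lower. All needles belonged to the set of leaves formed in 2010 and were taken at about noon. The series thus follows that set, not single leaves, through a full year at a fixed time of day. The 66 libraries analysed here are out of 73 that the series' design text counts. A date had 5 trees from October 2010 to 10 Mar 2011 (4 on 23 Feb), 4 trees from April to August 2011, 2 on 7 Sep and 3 on each of 7 Oct and 26 Oct 2011. CCTO44 was sampled on all 16 dates, CCTO46 and CCTO90 on 14, CCTO89 on 13, and CCTO43 on 9, none of them between 10 Mar and 7 Oct 2011. Each replicate of a date is thus a separate tree, but the libraries of a date also share the weather of that day.

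Library totals ran from 9924771 to 37373284 counts with a median of 20944426. The smallest library was CCTO46 on 9 Nov 2010. A total of 3 counts, the limit that a count of 0 allows, stood for 0.302 CPM in the smallest library and 0.0803 CPM in the largest. Of 199471 transcripts in the count table, 60931 had enough counts to be tested, and they held 99.7% of all counts. The files do not pair the transcript identifiers with gene names, so no gene group could be followed, and transcripts are given by identifier.

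The needle transcriptome was spread over more transcripts in winter than in summer. At an equal depth of 9924771 counts per library, 79620 ± 2240 transcripts were detected on 6 Jan 2011 (SD, n = 5) and 60600 ± 2820 on 17 Jun 2011 (n = 4). The 20 most abundant transcripts held 9.34% ± 0.887 of all counts on 6 Jan and 27.1% ± 3.32 on 17 Jun. Every library of 6 Jan lay apart from every library of 17 Jun in both measures (two-sided exact permutation test, p = 0.00794, the smallest that 5 against 4 libraries can give, adjusted p = 0.0119 over 3 measures). That test takes the 9 libraries as independent; within the 4 trees of both dates the direction was the same in 4 of 4, where an exact sign-flip test gives p = 0.125, the smallest it can give. The last measure, the share of 4 abundant transcripts that rose and fell together within dates, did not separate the dates: 1.03% ± 0.332 against 5.32% ± 5.88, exact permutation p = 0.167. In the CCTO43 library of 26 Oct 2011 this share reached 38.24% and the 20 most abundant transcripts held 48.33% of the counts, the highest of all 66 libraries in both.

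**Figure D1:**
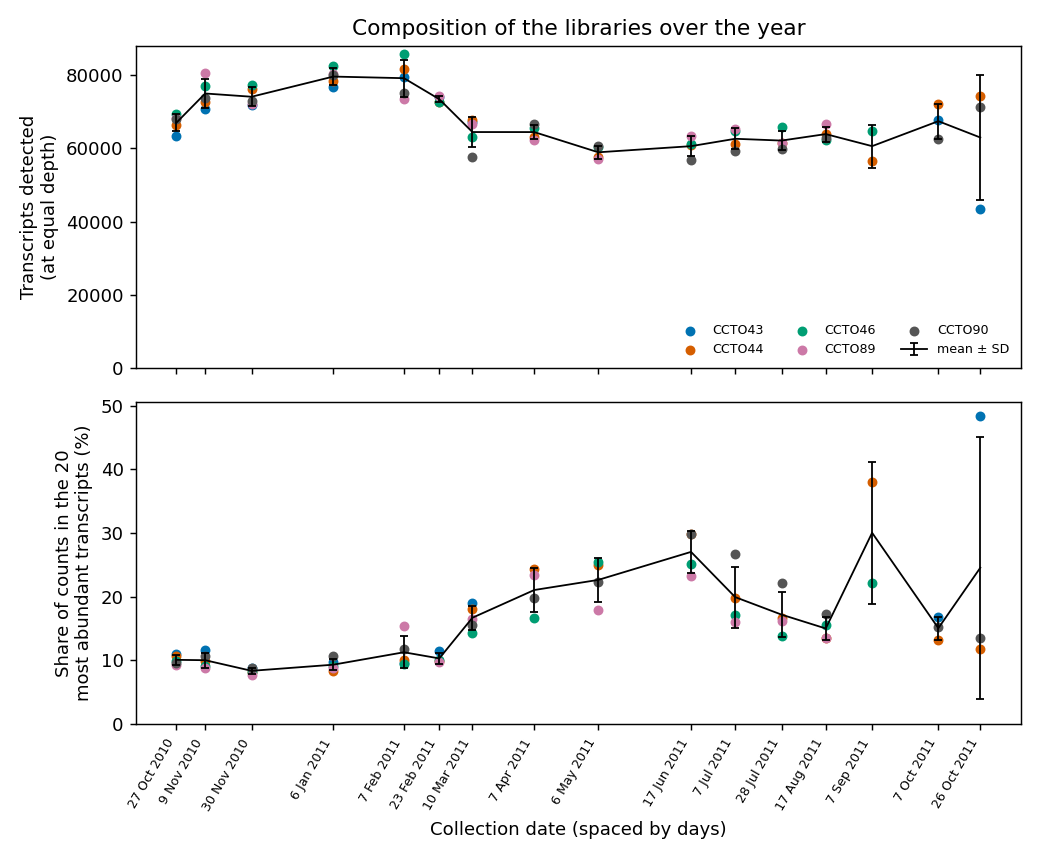
Transcripts detected at an equal depth of 9924771 counts (top) and percent of counts in the 20 most abundant transcripts (bottom) for each of the 66 libraries, by collection date, with points for single libraries coloured by tree and a line for the date mean ± SD. Detected transcripts fell from 79620 on 6 Jan to 60600 on 17 Jun, and the CCTO43 library of 26 Oct 2011 lies apart from the other libraries of its date in both panels.

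Nearly every transcript that could be tested changed in abundance over the year. Between the 16 dates, with the tree as a block, 56249 of 60931 transcripts (92.3%) differed, and 52697 (86.5%) passed the test of a curve with 1 cycle per year (edgeR quasi-likelihood F tests, Benjamini-Hochberg adjusted p under 0.05). Only 1 year and 1 set of leaves were followed, so whether such a curve repeats is not known. It cannot be told apart from a change with the age of the leaves or one particular to that year. Between 27 Oct 2010 and 26 Oct 2011, 18334 transcripts (30.1%) differed. The fitted curves were wide: the median ratio of peak to trough was 3.58-fold, 42543 transcripts reached 2-fold, 23831 reached 4-fold and 9793 reached 10-fold. Of the fitted peaks, 25695 fell between the autumn and the spring equinox and 27002 between the spring and the autumn equinox. Scaling centres the changes of most transcripts, so this balance is partly set by it: the share between the autumn and the spring equinox was 48.8%, 51.8% by RLE size factors and 51% by the upper quartile. It was 58.3% without a filter on low counts and 48.5% to 52.4% under all other alternatives. Among the curves of at least 10-fold the winter peaks were more numerous, 5927 against 3866.

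The peaks of the fitted curves gathered around the solstices, but the highest dates did so in winter only. Of the 52697 transcripts, 55.1% had the fitted peak within 30 days of a solstice, windows that cover 32.9% of the year, and 18.1% peaked within 30 days of an equinox. The winter solstice had 29.6% and the summer solstice 25.4%. The date of the highest level was compared, after the data were seen, in 4720 transcripts of at least 10 CPM with a range between dates of at least 4-fold. It lay within 30 days of the winter solstice, on 30 Nov or 6 Jan, in 25.2% of them. Within 30 days of the summer solstice, on 17 Jun or 7 Jul, it lay in 7.3%. Of the 4720, 4572 were called as annual curves, and 26.7% and 37.2% of these curves peaked within 30 days of the winter and the summer solstice. A fitted peak near the summer solstice is thus mostly not the date of the highest level. When the curve was fitted within each of the 4 trees with 13 or more dates, the solstice share of the same transcripts lay between 48.9% and 52.2% (SD between trees 1.62 percentage points). In 38277 transcripts (72.6%) the curve of each of these trees peaked within 45 days of the joint curve. Because libraries of a date share that day, the curve was also fitted to the 16 date means, where 40379 transcripts passed with limma and 60.9% of them peaked near a solstice. A smaller crest in mid-September, 1167 transcripts of at least 4-fold, came mostly from 1 library: 1044 of them were highest in CCTO43 on 26 Oct 2011, and 238 transcripts peaked there when that library was left out.

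**Figure D2:**
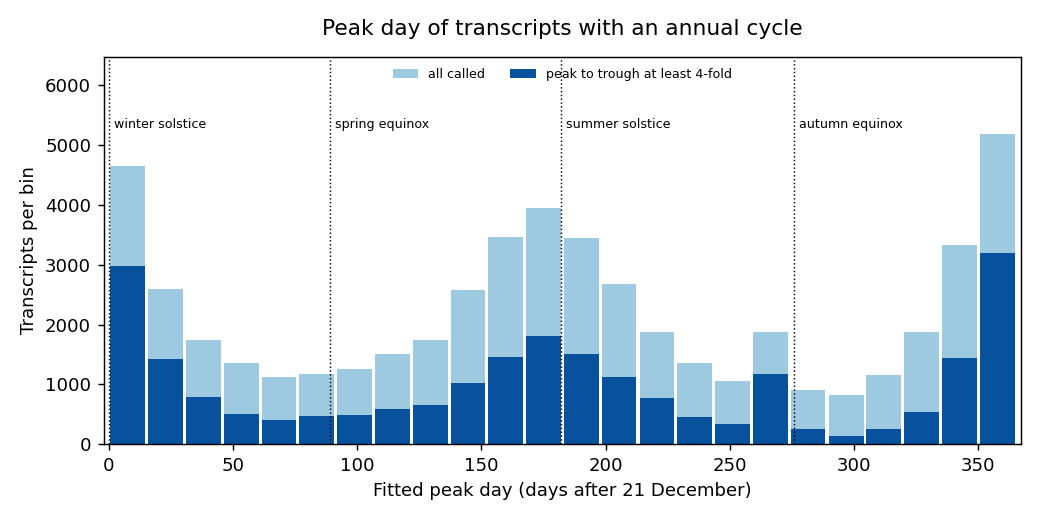
Number of transcripts by fitted peak day, in days after 21 December, for the 52697 transcripts called as annual curves (light bars) and the 23831 of them with a peak-to-trough ratio of at least 4-fold (dark bars). Dotted lines mark the solstices and equinoxes; 55.1% of the peaks lie within 30 days of a solstice.

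The widest winter curve was that of psme_t070199. It stood at 3.40 ± 1.64 CPM on 27 Oct 2010 (SD, n = 5), 656 ± 309 on 30 Nov, 3440 ± 1080 on 6 Jan, 104.9 ± 53.9 on 10 Mar and 0.395 ± 0.32 on 17 Jun (n = 4), with a fitted peak on 18 Jan and an amplitude of 7.84 on the log2 scale (edgeR quasi-likelihood F test, Benjamini-Hochberg adjusted p = 1.71e-31). Next came psme_t075233 with an amplitude of 7.81 and a peak on 17 Jan (adjusted p = 3.93e-31, same edgeR test). The widest summer curves were those of psme_t111352, which peaked on 12 Jul with an amplitude of 4.56 (adjusted p = 2.43e-20, edgeR), and psme_t044566, which peaked on 27 Jul with an amplitude of 4.54 (adjusted p = 1.05e-16, edgeR). psme_t044566 rose from 81.3 ± 18.1 CPM on 17 Jun (n = 4) to 2458 ± 541 on 28 Jul (n = 4) and was at 5.99 ± 2.57 on 7 Oct (n = 3) and 163.9 ± 73.9 on 26 Oct (n = 3). The separate curves of the 4 trees peaked within 13 days of the joint curve for all 4 transcripts. The p-values of these curves take the 66 libraries as independent. Over a sample of transcripts, the residuals of libraries of the same date correlated by 0.35, so these p-values may be too small.

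**Figure D3:**
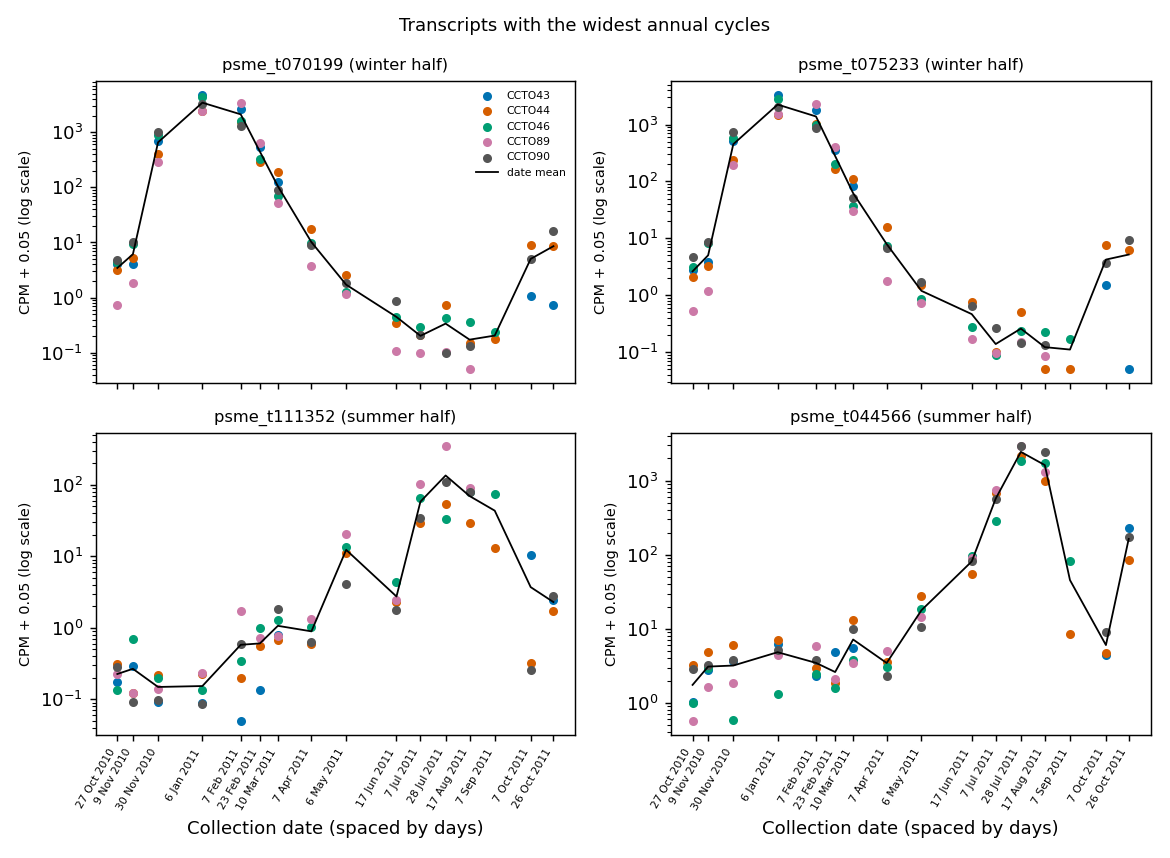
Abundance (CPM, log scale, 0.05 added) by collection date for the 2 transcripts with the widest curve in each part of the year, psme_t070199 and psme_t075233 (winter) and psme_t111352 and psme_t044566 (summer). Points are single libraries coloured by tree and the line joins the date means; psme_t070199 reached 3440 CPM on 6 Jan and psme_t044566 reached 2458 CPM on 28 Jul.

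An annual curve described the seasonal change only in part. It took a median of 54.5% of the variance between dates, and 2 cycles per year took 72.5%. In 24551 of the date-dependent transcripts (43.6%) it took less than 50%. The first principal component of the 5000 most variable transcripts, with 29.9% of their variance, moved with the season in each tree, but the libraries of 7 Oct 2011 lay nearer to those of winter than the libraries of 26 Oct 2011 did.

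**Figure D4:**
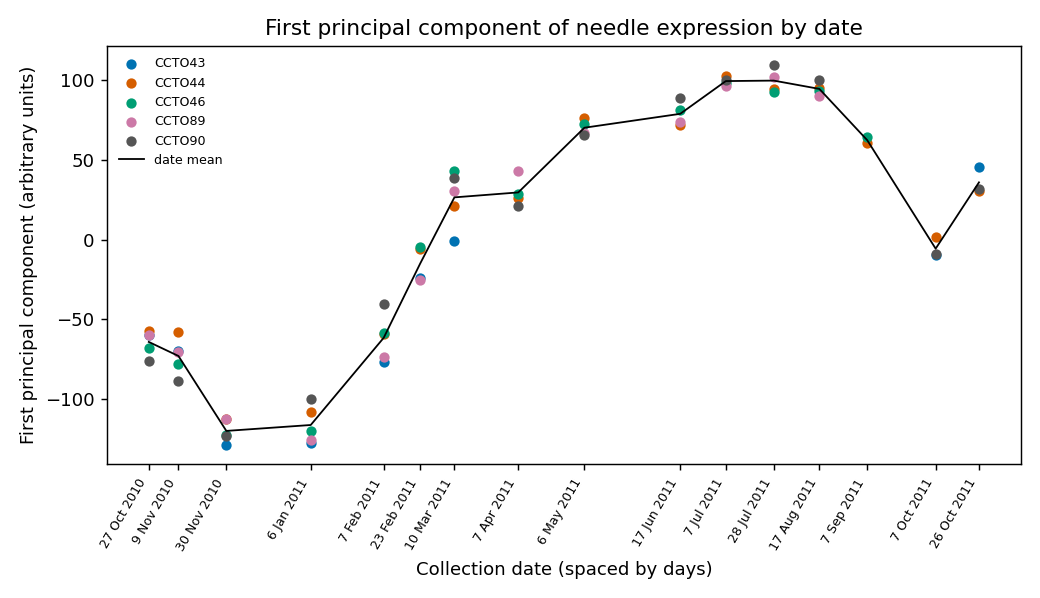
Score on the first principal component (29.9% of the variance, arbitrary units) of each of the 66 libraries by collection date, coloured by tree, with the date means joined by a line. The means run from -119.8 on 30 Nov 2010 to 99.5 on 28 Jul 2011; the mean of 7 Oct 2011 is -5.7 and that of 26 Oct 2011 is 35.8.

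The dates nearest the solstices, 6 Jan and 17 Jun 2011, differed in most of the transcripts tested. Compared with 17 Jun, 19259 transcripts were higher and 17259 lower on 6 Jan, together 59.9% of those tested (edgeR quasi-likelihood F test with the tree as a block, Benjamini-Hochberg adjusted p under 0.05, 5 against 4 trees). Changes of at least 2-fold numbered 16044 and 13771, and changes of at least 4-fold 10142 and 7063. The largest rises that had the same direction in all 4 trees with both dates were those of psme_t070199 (log2 change 13.14, SE 0.83, adjusted p = 1.75e-18, edgeR) and psme_t075233, which was at 2244 ± 818 CPM on 6 Jan (SD, n = 5) and 0.416 ± 0.287 on 17 Jun (n = 4; log2 change 12.44, SE 0.82, adjusted p = 1.83e-18, edgeR). The largest change in the other direction was that of psme_t020006, at 0.0309 ± 0.0488 CPM on 6 Jan and 104.4 ± 18.5 on 17 Jun (log2 change -11.47, SE 0.63, adjusted p = 3.6e-24, edgeR). It was followed by psme_t029262, at 0.0403 ± 0.0525 and 60 ± 8.19 CPM (log2 change -10.39, SE 0.6, adjusted p = 7.66e-24, edgeR). Their winter levels rest on 4 and 5 counts over 5 libraries, so the ratios of their counts, 3320 and 1520, have 95% exact Poisson intervals of 1290 to 12200 and 652 to 4690, which cover counting error only. Both were low on 27 Oct 2010 but not a year later. psme_t020006 stood at 0.0753 CPM on 27 Oct 2010 and at 35.6 on 26 Oct 2011, and psme_t029262 at 0.0506 and 20.9 CPM. Season, year and the age of the leaves can thus not be told apart for them.

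Dates of about equal day length in spring and autumn also differed widely. On 10 Mar 2011, 10909 transcripts were higher and 10004 lower than on 7 Oct 2011 (edgeR quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05, 5 against 3 trees), of which 8135 and 7218 changed by at least 2-fold. Compared with 7 Oct 2011, the changes of 10 Mar ran more often toward June than toward January. Of the transcripts higher in March, 5445 (49.9%) were also higher on 17 Jun than on 6 Jan, where 3090 would be shared by independent lists, and 1866 (17.1%) were higher on 6 Jan, where 3448 would be. Of the 10004 that were lower in March, 4271 were higher on 6 Jan and 1924 higher on 17 Jun, against 3162 and 2834 for independent lists. This direction holds against 7 Oct only. On the first principal component 10 Mar had a mean of 26.4, between 7 Oct at -5.7 and 26 Oct 2011 at 35.8, and the overlap was not computed against 26 Oct. psme_t150760 was at 58.2 ± 27.9 CPM on 10 Mar (SD, n = 5) and 0.905 ± 0.76 on 7 Oct (n = 3; log2 change 6.45, SE 0.82, adjusted p = 1.48e-08, edgeR), and psme_t027691 at 223 ± 196 and 2.87 ± 0.637 CPM (log2 change 6.32, SE 1.08, adjusted p = 9.12e-06, edgeR). In the other direction, psme_t016420 was at 0.269 ± 0.168 and 49.4 ± 22.4 CPM (log2 change -7.42, SE 0.52, adjusted p = 9.69e-16, edgeR) and psme_t026350 at 0.414 ± 0.461 and 50.5 ± 34.7 CPM (log2 change -7.3, SE 1.16, adjusted p = 2.47e-06, edgeR). These 2 depended on the choice of dates: with 7 Apr against 7 Sep 2011 psme_t016420 changed direction, to a log2 change of 0.66, and psme_t026350 lost its call (log2 change -1.73). Without the tree as a block 7198 transcripts were higher and 6649 lower, and without CCTO90 7103 and 6399. With only the libraries of these 2 dates in the fit, 5091 and 3968 passed.

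A year apart, on 27 Oct 2010 and 26 Oct 2011, needles of the set of leaves formed in 2010 differed in 18334 transcripts. On 26 Oct 2011, 9028 were higher and 9306 lower (edgeR quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05, 3 against 5 trees), of which 7394 and 5684 changed by at least 2-fold. The balance of directions depended on the scaling, with 10712 higher and 7467 lower by RLE size factors and 9627 and 8391 by the upper quartile. Compared with 27 Oct 2010, the changes of 26 Oct 2011 ran more often toward June than toward January: 6336 (68.1%) of the transcripts that were lower in 2011 were higher on 6 Jan than on 17 Jun, against 2941 for independent lists, and 4303 (47.7%) of those that were higher in 2011 were higher on 17 Jun, against 2557. psme_t152973 was at 29.3 ± 17.8 CPM on 27 Oct 2010 (SD, n = 5) and 0.199 ± 0.0734 on 26 Oct 2011 (n = 3; log2 change -7.53, SE 1.13, adjusted p = 6.43e-07, edgeR). psme_t029748 was at 16.6 ± 16.3 and 0.045 ± 0.078 CPM (log2 change -7.67, SE 1.7, adjusted p = 0.000401, edgeR). The later level of psme_t029748 rests on 2 counts over 3 libraries, so the ratio of its counts, 353, has a 95% exact Poisson interval of 97.5 to 2910 for counting error. psme_t158226 was at 83.8 CPM in CCTO43 in October 2010 and at 1360 ± 2230 CPM in October 2011 (edgeR adjusted p = 0.00463), and psme_t190191 at 234 and 1427 ± 2330 CPM (edgeR adjusted p = 0.00224). The other 4 trees had no count of either in October 2010, so their fitted log2 changes, 10.39 (SE 2.65) and 9.23 (SE 2.17), have no fixed size: they were 6.34 and 4.93 without the tree as a block, and 7.85 to 15.92 and 7.19 to 15.38 when 1 tree was left out. Neither call passed without CCTO43, without CCTO44 or without the block, and that of psme_t190191 did not pass with DESeq2.

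Of the 9028 transcripts that were higher in 2011, 1241 belong to a group of rare transcripts concentrated in the CCTO43 library of 26 Oct 2011, and without that library 6799 were higher and 6885 lower. With 7 Oct 2011 in place of 26 Oct 2011, a choice made after the data were seen, 5705 were higher and 5830 lower. Of these 5830, 4551 (78.1%) were higher on 6 Jan than on 17 Jun, against 1843 for independent lists, and 2858 (50.1%) of the 5705 were higher on 17 Jun, against 1616. On the first principal component 7 Oct 2011 lay nearer to winter than 26 Oct 2011, with means of -5.7 and 35.8, and the libraries of 26 Oct 2011 were placed early in the year by their transcripts, by -31.7 ± 10 days (SD, n = 3). The year, the age of the leaves and the weather of the days change together here.

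Change between successive dates was uneven over the year. In 4 intervals about 20% of the transcripts changed: 12650 between 7 Apr and 6 May 2011, when 5560 rose and 7090 fell, 12460 between 23 Feb and 10 Mar, 12321 between 6 Jan and 7 Feb, and 11996 between 17 Jun and 7 Jul (edgeR quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05, 4 or 5 trees per date). These 4 counts were too close to rank, since without CCTO43 the first and the last were both 12828. In contrast, 107 changed between 7 and 28 Jul and 763 between 6 May and 17 Jun, the longest interval at 42 days. Between 28 Jul and 17 Aug a single transcript passed with edgeR, and 2312 had an unadjusted p under 0.05. The intervals before and after 7 Sep, with 8567 and 8658 transcripts, rest on the 2 trees of that date and fell to 3346 and 2448 without CCTO44, and to 5401 and 4826 without CCTO46. These 2 trees are also those whose libraries of 17 Aug resembled each other's tree: with the 17 Aug labels exchanged 9241 and 9935 passed, and with these libraries left out 5367 and 9668.

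Several of these counts depended on single trees. Between 23 Feb and 10 Mar 7598 transcripts passed without CCTO90, and between 17 Jun and 7 Jul 7549, 7169 and 7504 passed without CCTO44, CCTO46 and CCTO89. Between 6 May and 17 Jun 235, 130 and 364 passed without CCTO44, CCTO46 and CCTO90, and between 7 and 28 Jul 63, 71 and 63. Between 28 Jul and 17 Aug 216 passed without CCTO44 and 144 without CCTO46, the trees whose libraries of 17 Aug resembled each other's tree, and with the tree labels of these libraries exchanged 4 passed.

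Between 7 Apr and 6 May psme_t028834 rose from 0.0515 ± 0.0595 CPM on 7 Apr (SD, n = 4) to 3.29 ± 4.21 on 6 May (n = 4; log2 change 5.7, SE 1.41, adjusted p = 0.00229, edgeR), and psme_t019443 from 0.294 ± 0.26 to 9.17 ± 14.6 CPM (log2 change 4.67, SE 1.5, adjusted p = 0.0204, edgeR). The 7 Apr level of psme_t028834 rests on 5 counts, so the ratio of its counts, 59.2, has a 95% exact Poisson interval of 25 to 184 for counting error. On 6 May it stood at 3.71 and 9.08 CPM in CCTO44 and CCTO46, but at 0.223 and 0.129 CPM, near the floor, in CCTO89 and CCTO90. The call of psme_t028834 was lost without CCTO46 (log2 change 5.04), and that of psme_t019443 without CCTO44 (5.18), without CCTO89 (2.44) and without a filter on low counts (4.63). psme_t010945 fell from 48.9 ± 18.7 to 1.33 ± 0.274 CPM (log2 change -5.17, SE 0.46, adjusted p = 1.15e-11, edgeR) and psme_t088647 from 15.3 ± 7.05 to 0.58 ± 0.303 CPM (log2 change -4.7, SE 0.42, adjusted p = 7.14e-12, edgeR). Without the tree as a block 7825 transcripts passed in this step, and of the other 14 steps 13 also fell by more than 1.5 times.

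**Figure D5:**
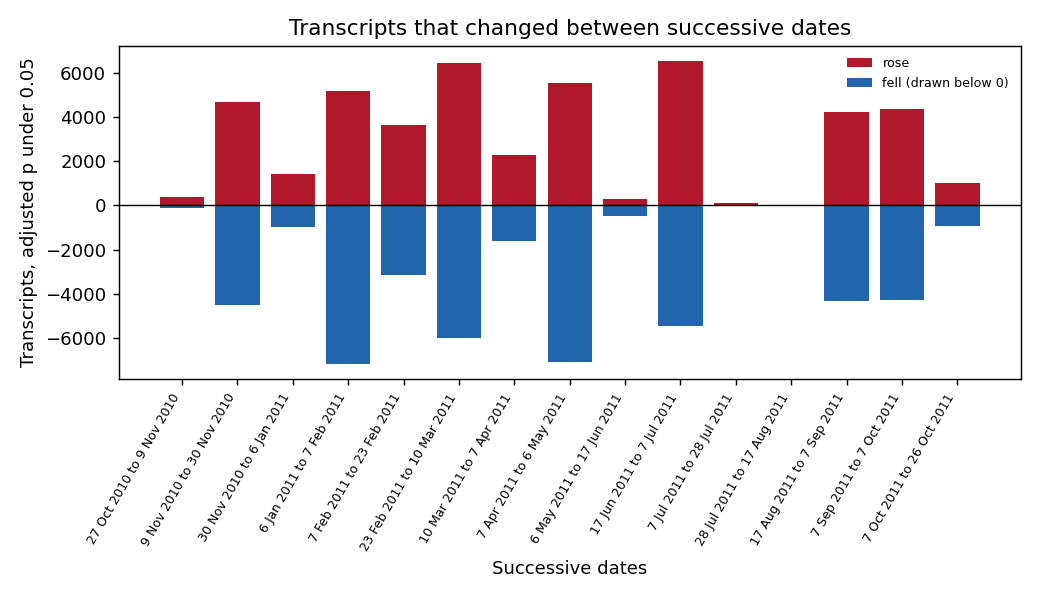
Number of transcripts that rose (above 0) or fell (below 0) between each pair of successive dates, at an edgeR quasi-likelihood adjusted p under 0.05. Between 7 Apr and 6 May 2011 5560 rose and 7090 fell, and a single transcript passed between 28 Jul and 17 Aug.

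The 5 trees differed from one another in many transcripts. With the dates in the model, 46419 of 60931 transcripts (76.2%) differed between trees (edgeR quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05), and 42299 of these also differed between dates. In 595 of the 11843 transcripts of at least 10 CPM the trees differed significantly and by at least 4-fold. Of all transcripts tested, 84 had a median of at least 10 CPM in 1 or more trees and a median of 0 in another, and 25 of these had a median of 0 in 4 trees. The trees were sampled on different dates, CCTO43 never in summer, so part of these differences may be seasonal: with medians over the 6 dates that all 5 trees share, chosen after the data were seen, 83 transcripts were found, 59 of them among the 84, and 21 had a median of 0 in 4 trees. These values describe the 5 individuals; each seed locality is represented by 2 or 3 trees.

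The form of the annual curve was compared between CCTO44, CCTO46, CCTO89 and CCTO90. The tree by season terms passed in 1610 transcripts (2.6%; edgeR quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05), and 7487 had an unadjusted p under 0.05. In the simulation, the test recovered 25% of curves of 2-fold peak to trough that were turned upside down in CCTO90. That is a larger difference between trees than 2-fold, and few transcripts were changed there. Smaller differences may thus be missed. The libraries labelled CCTO44 and CCTO46 on 17 Aug 2011 resembled each other's tree rather than their own, and 945 transcripts passed when they were left out and 1024 when their tree labels were exchanged. Without CCTO46 758 passed, and without CCTO44 1018.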

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

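The regroupings of libraries and the tests of explanations in this part were chosen after the results they bear on had been seen. Libraries were set apart where 1 value lay far from the other 3 or 4 of its date, relative to their range. Among 76 sets 6 such values were found. The limits used are meant to give about 1 in 20 sets by chance under a normal spread, which was not checked for these values.

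The libraries labelled CCTO44 and CCTO46 on 17 Aug 2011 appear to carry each other's tree label. Outside that date, 285 transcripts had counts in every CCTO44 library and in no CCTO46 library, and on 17 Aug the library labelled CCTO44 had 13 of them (4.6%) and the one labelled CCTO46 all 285. Of 193 transcripts found in every CCTO46 library and in no CCTO44 library, the library labelled CCTO44 had 190 (98.4%) and the one labelled CCTO46 had 10 (5.2%). Mixed RNA of both trees is argued against by those 4.6% and 5.2%, so an exchange of labels remains the candidate explanation, with a partner out of place on each side. No biological explanation was tested; the exchange lowers the number of transcripts with tree by season terms from 1610 to 1024.

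A group of 1289 rare transcripts had over 30% of their summed CPM in the CCTO43 library of 26 Oct 2011. They held 2.37% of its counts against a median of 0.0343% in the others, and no other library had more than 131 such transcripts. The group's share was also above that median in every other library from September 2011 on. It was 0.305% and 0.158% in CCTO44 and CCTO46 on 7 Sep, and 0.148%, 0.135% and 0.425% in CCTO43, CCTO44 and CCTO90 on 7 Oct. On 26 Oct it was 0.1% in CCTO44 and 0.172% in CCTO90. On 17 Jun it was at most 0.0124%, and before September it reached 0.246%, in CCTO43 on 10 Mar. In the other 65 libraries the group kept its internal proportions within counting error, with a median chi-square per degree of freedom of 1.06, while 100 random sets of like abundance gave 5.71 to 6.44, which argues against a response of genes of the tree that vary like others of their abundance. Carry-over from this library as the whole source is argued against in the 57 libraries of other trees: transcripts of CCTO43 alone outside the group, chosen without the library tested, had at most 27.9% of the counts that it would bring in each of the 53 before October 2011 and at most 40.9% in each of the 4 of October 2011 (for the latter without psme_t158226 and psme_t190191), each below by more than counting error. Before October 2011 this rests almost wholly on psme_t158226 and psme_t190191, which had no count in these 53 libraries. Where the fewest counts were due, 97.2, they would bring 46.9 and 49.1 of them. The 81 counts behind the 27.9%, in CCTO44 on 10 Mar, are of other transcripts. In the other 8 libraries of CCTO43 carry-over stays open. In 3, 1 and 0 of them at least 5 transcripts outside the group lay below 100%, 50% and 25% of the counts that carry-over would bring. A source of fixed composition may also be DNA or RNA of another organism. All 1241 of the tested members were called higher in October 2011 and 1235 were called as annual curves.

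The transcripts psme_t158226 and psme_t190191 were found in all 7 CCTO43 libraries before October 2011 and had no count in the 53 libraries of other trees before then, which allows up to 0.00267 CPM. In October 2011 they appeared in the other trees too: psme_t158226 stood at 5130 CPM in CCTO90 and 2.4 in CCTO44 on 7 Oct, and at 117 and 23.9 CPM on 26 Oct. Carry-over of CCTO43 RNA is argued against in CCTO90 on 7 Oct. There psme_t158226 stood above its highest CCTO43 level, 3940 CPM, and 1 of the other 114 transcripts with the same earlier pattern was detected. In CCTO44 on both dates and CCTO90 on 26 Oct carry-over stays open, though at most 18 of the 114 were detected. psme_t158226 had 53 to 1733 counts there against 28192 in CCTO43 on 26 Oct, a share that would bring few counts of the 114. A CCTO43 library under another label is argued against by a detected share of at most 17.2% in any of these 4 libraries. RNA that the trees do not encode, such as that of an infectious agent, is a possible explanation that was not tested, since it needs the sequences. On 27 Oct 2010 CCTO43 stood apart for both transcripts, at 83.8 and 234 CPM against 0 in the other 4 trees.

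Other values that stood apart are given without explanation. CCTO46 on 9 Nov 2010 had 9924771 counts, where the next lowest of the date had 21281050. CCTO90 on 10 Mar 2011 had 37373284 counts, where the next highest had 21050717. On 23 Feb 2011 the 20 most abundant transcripts held 11.56% of the counts in CCTO43 and at most 10% in the other 3 trees. psme_t019443 stood at 31.1 CPM in CCTO89 on 6 May 2011 and at most at 2.8 CPM in the other 3 trees. The annual curve differed between 4 trees in 1610 transcripts by the test of the difference itself.

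Regrouped libraries were tested with limma on log2 CPM, which gives somewhat other counts than edgeR. Chance is excluded where fewer than 1 in 20 groupings called as many transcripts as the real one. It was excluded for the dates (52993, highest other 8117) and the annual curve with whole dates shuffled (50570, highest other 38269). It was also excluded for the trees (43645, highest other 918) and the tree by season terms (1921, highest other 45). In each of these only the real grouping, 1 of 100, reached its count. For winter against summer (34500, highest other 29398) only the real grouping of 100 reached its count. The same held, at 1 of 56, for March against October (19877, highest other 12447) and for the 2 Octobers (19059, highest other 4832). Chance is not excluded for these contrasts of dates. Groupings that part as many trees as the real one numbered 14, 7 and 7 besides it, too few for a share under 0.05. Among those groupings the highest others were 29394, 6791 and 3512. The remaining groupings keep both dates of at least 1 more tree on the same side. Where the dates differ in their number of trees, as in these contrasts, the groupings can include one that swaps the dates in every tree with both. That is nearly the real contrast with its sign reversed. The highest others may thus hold the real difference, and which grouping gave them was not examined. The shuffled dates gave a median of 6748 annual curves, so libraries of a date are not independent in that test. For the 2 seed localities, 297 transcripts passed with a highest other of 15, but 10 splits of 5 trees are too few for a share under 0.05.

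Among the steps between dates with 3 or more trees, only the real grouping reached its count in each of the 10 steps from 27 Oct 2010 to 7 Jul 2011. The largest had 12380 transcripts and a highest other of 3428. Chance is not excluded for these steps either. Groupings that part as many trees as the real one numbered 7 to 12 besides it, too few for a share under 0.05. From 10 Mar to 7 Apr 1 of these called 2108 transcripts against the real 3035. These dates differ in their number of trees, so that grouping may be the one that swaps the dates in every tree with both. It need then not be a draw of chance. For 7 to 28 Jul 2 of 35 groupings called as many as the real 95 and the highest other called 115. For 28 Jul to 17 Aug, 18 of 35 called as many as the real 4, and the highest other, 3142, points to a structure of the samples other than the 2 dates; among the 7 groupings that part as many trees the highest was 1319. For 7 to 26 Oct 2011 the 10 splits of 6 libraries are too few for a share under 0.05; 2661 transcripts passed and the highest other was 2542.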

How the results depend on the processing

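Alternatives were chosen before the data were examined, except those that leave out or relabel libraries of 17 Aug or October 2011, restrict the transcripts to those of the normalized table, leave out transcripts concentrated in 1 library, put one October date in place of another, or take tree medians over shared dates, which were chosen after the data were seen. Counts within 1.5 times of the reported one are taken as unmoved, as are shares within 1 SD between trees of it (1.62 percentage points for the solstice share, 1.05 for the share by season), and the cause of the moves below was not tested unless fewer transcripts or libraries in the test are named.

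With a mean of at least 5 CPM fewer transcripts were tested, and 16297 differed between dates, 15184 followed an annual curve, 6596 and 6138 were higher and lower in winter than in summer, 4531 and 4704 in March than in October, 3914 and 3720 in October 2011 than in 2010, 6889 changed from 7 Apr to 6 May, 12884 differed between trees and 134 had tree by season terms. With only the transcripts of the normalized table the counts were 34866 for dates, 31856 for the annual curve, 12366 higher in winter, 27727 for trees and 394 for tree by season terms. Without a filter 94154 transcripts followed an annual curve and 59.4% of them peaked near a solstice.

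Without the tree as a block, 7198 and 6649 transcripts were higher and lower in March than in October and 7825 changed from 7 Apr to 6 May. Leaving out each tree in turn gave 758 to 1151 transcripts with tree by season terms (CCTO43 is not in that test), 53.7% to 57.2% of peaks near a solstice, and 7103 to 10326 higher and 6399 to 9572 lower in March than in October. With only the libraries of the 2 dates 5091 and 3968 passed there. The tree by season terms passed in 945 transcripts without the 17 Aug libraries of CCTO44 and CCTO46 and in 1024 with their labels exchanged. At an adjusted p under 0.01, 5932 transcripts were lower in October 2011, 7554 changed from 7 Apr to 6 May and 680 had tree by season terms, and 5684 were lower in October 2011 by at least 2-fold. With 7 Oct in place of 26 Oct 2011, 5705 were higher and 5830 lower.

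The solstice share was 60.9% from date means, 59.3% with the date as a correlated block (correlation 0.35), 51.7% with 2 cycles per year and 52.1% from the interpolated values. With 7 Apr against 7 Sep in place of March against October, psme_t016420 changed direction, to a log2 change of 0.66. RLE moved the median log2 change of all transcripts by 0.11 for winter against summer and by 0.13 for October 2011 against 2010, where 58.9% of the calls were then higher instead of 49.2%. Over all alternatives, 214 counts and shares that answer a comparison were unmoved and 40 moved; among single steps, named transcripts and shares by season 580 were unmoved, 12 lost their call, 1 changed direction and the rest moved. The set tests on gene lists were not run, since no identifier has a name. Depth limits the values of transcripts with few counts on a date, and the smallest library allows up to 0.302 CPM at a count of 0.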

Other observations

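The tests in this part were chosen after the data were seen. Among the 11843 transcripts of at least 10 CPM, 4720 differed between dates with a range of at least 4-fold between the highest and the lowest date. Their maxima were spread unevenly: 15.4% were highest on 6 May, 14.8% on 30 Nov, 10.4% on 6 Jan and 8.9% on 7 Sep, but 4.2% on 17 Jun and 3.1% on 7 Jul, and minima were most frequent on 6 Jan, with 19.4%. In 946 of them a curve of 1 cycle per year took less than 50% of the variance between dates, and these were most often highest on 7 Sep, with 15.4%, a date of 2 trees, and on 30 Nov, with 12.7%. The single most abundant transcript over all libraries, psme_t083272, chosen after its values were seen, held 0.57% ± 0.0936 of the counts on 7 Feb 2011 (SD, n = 5), 3.36% ± 1.38 on 10 Mar (n = 5), 4.75% ± 1.88 on 17 Jun (n = 4), 1.06% ± 0.251 on 17 Aug (n = 4) and 0.609% ± 0.232 on 7 Oct (n = 3), and on 7 Sep the 2 trees had 2.77% and 8.81%.

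Each library's place in the year was read from 2000 transcripts with curves fitted to the other dates. The median absolute error was 12 days over all 66 libraries. The 3 libraries of 26 Oct 2011 were placed early, by -31.7 ± 10 days (SD, n = 3), and no other date had a mean error beyond 24.5 days in either direction. With both dates of October 2011 left out of the curves, the libraries of 26 Oct were placed at -44, -23 and -28 days from their date and those of 7 Oct at 5, -2 and 1 days. Within each of the 3 trees the library of 7 Oct was thus placed later in the year than the library of 26 Oct. Such a reversal is not particular to October: with 1 date at a time left out of the curves, the libraries of 10 Mar and 7 Apr were placed in reverse order in 4 of 4 trees, and those of 6 May and 17 Jun in 2 of 4. The mean absolute error of these 6 libraries was 17.2 days with the dates as labelled and 15.2 days with the 2 dates exchanged, a difference below the median error, so the values do not decide between the 2 assignments.

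Of the 4 abundant transcripts that rose and fell together within dates, psme_t001906, also chosen after its values were seen, had the most counts. On 17 Jun 2011 it held between 0.154% and 6.08% of the counts of a library (n = 4), on 7 Jul between 0.206% and 0.243% (n = 4), and in CCTO43 on 26 Oct 2011 20.3%. Within dates its log2 abundance correlated with that of the other 3 across 66 libraries by construction, since the group was chosen at a correlation of at least 0.9 with it. Trees took 11.1% of the variance of the group's share within dates (permutation test of trees within dates with 10000 resamples, p = 0.226).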
